A study of Mus musculus with 12 samples.

How the data were processed

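RNA was sequenced from mouse cumulus cells, the somatic cells that surround the oocyte, in 3 libraries from cells given FSH and FBS over 18 hours and 3 labelled as untreated. The small-RNA libraries of the series were not analysed here. Per the file headers, each deposited table lists transcript events (first exons, last exons, cassette exons, retained introns and others) with their position and an FPKM value. Reads were aligned with HISAT2 2.0.1, per the submitters' processing notes; the assembler, its filters and the genome build were not given in the sources used here. The tables list no event at 0, so for gene values an event missing from a library was treated as missing and not as 0. The depth of the libraries is unknown, because the files hold FPKM and no counts, and no counting interval is given. Replicates are libraries that the labels number within a group. Nothing says that they came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

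A gene's value in a library was the larger of its summed first-exon FPKM and its summed last-exon FPKM on the strand that carried most of its signal. Symbols came from the supplied table of gene names, which matched 13281 of 13318 genes. Of 12768 genes compared, 98.98% overlapped their position in a RefSeq table of another source, which was used only for this check and for the gene class.

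Libraries of a group were compared before they were averaged. Over 2045 genes whose first-exon and last-exon sums differed by at most 0.1% in every library, the variance of the log ratio of each pair of libraries was fitted as a part that shrinks with the FPKM, as counting noise does, plus a constant part. The selection was on agreement within a library and not between libraries. The constant part, written as a CV per library, was 1.53% between FSH and FBS libraries 1 and 2 and 2.18% between untreated libraries 1 and 2. It was 21.6% to 31.7% between library 3 and the other libraries of its group. Over all 9022 genes tested it was 3.14%, 3.76% and 23.5% to 33.4%. With no counts, a chi-square test could not be run, and some genes differed between libraries 1 and 2 by more than 2-fold. Libraries 1 and 2 of each group were averaged and counted as 1 sample, so n is 2 per group throughout.

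The fit fixed before the data were examined took all 6 libraries as separate replicates. It was replaced as the lead fit once this closeness was found and after its own calls had been seen, because repeat measurements counted as replicates make p-values too small; its counts are given beside the lead counts. The test itself was as fixed: limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, over the 9022 genes listed in all 6 libraries with a mean of at least 1 FPKM. A fold change on this scale understates the change of low genes. On simulated data with 2 samples per group and 200 changed genes among 9022, over 20 runs, the fit recovered 0% of 2-fold, 15.2% of 4-fold, 67.2% of 16-fold and 79.6% of 32-fold changes, and 2.19% of its calls were false. The simulated noise was independent between genes and between samples. In the data, same-numbered samples deviated together (r = 0.51 over genes after averaging), so these shares, that of false calls among them, may not hold. A gene that does not pass is therefore not shown to be unchanged.

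Gene lists fixed before the data were examined were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists with at least 3 tested members; a camera p asks whether a list's genes moved more than the other genes. None of the 25 lists passed with an estimated correlation, which rests on few samples. That form of the test has only the residual degrees of freedom of 4 samples, so small p-values are hard to reach. For steroid hormone genes the camera p went from 3.47e-08 to 0.029, although their estimated correlation of -0.033 lay below the preset one. For that list, not passing therefore does not show that correlation between genes made the result. Other lists had estimated correlations far above the preset one. They were 0.84 for ribosomal protein, 0.52 for inflammatory, 0.33 for SMAD and 0.27 for cumulus expansion genes. For those, correlation between genes and few degrees of freedom cannot be told apart. The lists of mitochondrially encoded genes and of oocyte, endothelial and erythroid markers had fewer than 3 tested members and were not tested. The genes picked for naming were the 10 largest rises and 10 largest falls among called genes whose 3 libraries of one group all lay above those of the other, with a mean of at least 5 FPKM in the higher group and leaving out predicted genes and pseudogenes; Has2, Ptgs2, Tnfaip6, Ptx3, Bax, Bcl2 and Fas among others in any case; and up to 4 tested members per list with the smallest adjusted p. Some genes so picked are not reported here, among them a long transcript under a microRNA symbol. Other genes named were chosen after their values were seen, and the text says so.

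The retained share of an intron was the FPKM of the form that keeps it over the sum of both forms, for introns with a sum of at least 1 FPKM in all 6 libraries. In these shares and those of cassette exons, a form that a library did not list counted as 0. Shares were compared with an exact permutation test, two-sided; with 2 samples against 2 it cannot give a p under 0.333 and decides nothing. This measure was chosen after the tables had been seen. Alternatives covered the pseudocount, the filter, 3 rescalings, the replicate block, each library left out, limma without trend, array weights, the gene class, the gene value and the treatment of libraries 1 and 2. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and figures.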

Results

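Cumulus cells that had received FSH and FBS over 18 hours were compared with cells labelled as untreated. The labels give no time in culture for the untreated cells, so a difference in culture time cannot be told apart from FSH and FBS. FSH is a gonadotropin that can drive cumulus expansion, the deposition of a hyaluronan matrix between the cells, and FBS is fetal bovine serum. Both were given together, so the effect of FSH cannot be told apart from that of FBS. The series concerns the expansion and the apoptosis of these cells. Its design text also describes complexes whose oocyte was removed, and the labels do not say whether the untreated libraries came from them. Each group held 3 libraries. In both groups libraries 1 and 2 differed far less than the other pairs within a group. Over 2045 genes whose first-exon and last-exon sums matched within 0.1%, the CV beyond noise that shrinks with the FPKM was 1.53% in FSH and FBS and 2.18% in untreated cells, against 21.6% to 31.7% for the other pairs. Over all 9022 genes tested it was 3.14% and 3.76%, against 23.5% to 33.4%, and 2.82% and 4.54% of genes differed more than 2-fold, against 13.8% to 22.7%. Libraries 1 and 2 were averaged and counted as 1 sample, and n is 2 per group. The tables listed 10475 to 11398 genes in the FSH and FBS libraries and 10786 to 11552 in the untreated ones, at an unknown sequencing depth.

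After FSH and FBS 3 of 7 tested genes of cumulus expansion, 5 of 11 of the steroid hormone list and 6 of 20 of cholesterol synthesis and uptake were called higher. The growth factor gene Ccn2 fell most. The steroid hormone list also holds genes of cholesterol uptake and esterification and of progesterone inactivation. None of these lists passed with an estimated correlation between genes, a form of the test that 4 samples leave weak. Tnfaip6, whose product links hyaluronan to heavy chains in the expanding matrix, rose from 2.01 ± 1.01 to 79.6 ± 41.5 FPKM (SD, n = 2; log2 fold change 4.68, SE 0.47, limma adjusted p = 0.0053). Ccn2, which encodes connective tissue growth factor, fell from 259.7 ± 105.7 to 2.36 ± 1.65 FPKM (SD, n = 2; log2 fold change -6.31, SE 0.47, limma adjusted p = 0.0029). Of 9022 genes tested with limma, 152 were higher and 62 lower, and in all 214 both samples of one group lay above both of the other, as selection by this fit favours; so did 48.1% of all genes tested, against 33.3% by chance. The fit fixed before the data were examined, with all 6 libraries as separate replicates, called 973 higher and 350 lower; its p-values are too small if libraries 1 and 2 are repeat measurements. The median log2 fold change of all genes was 0.24, so a gene at that value moved with the bulk. Relative to it Tnfaip6 rose by 4.44 and Ccn2 stood at -6.55. Rescaling by median of ratios took the median to 0.0043 and the calls to 49 higher and 41 lower, so that 54.4% of called genes were higher in place of 71.0%. Under all 3 rescalings 33 of the higher and 31 of the lower calls were kept. Leaving out untreated library 3 left 42 higher and 33 lower, and leaving out FSH and FBS library 3 gave 253 and 131. Of 45 named genes with a call, 21 did not pass without untreated library 3: Spp1, Ptgs2, Ptx3, Runx1, Runx2, Scarb1, Soat1, Fdx1, Msmo1, Sqle, Ldhb, Ndrg1, Ero1l, Asns, Herpud1, Gstm1, Srxn1, Mt2, Timp1, Tnc and Acta2.

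**Figure D1:**
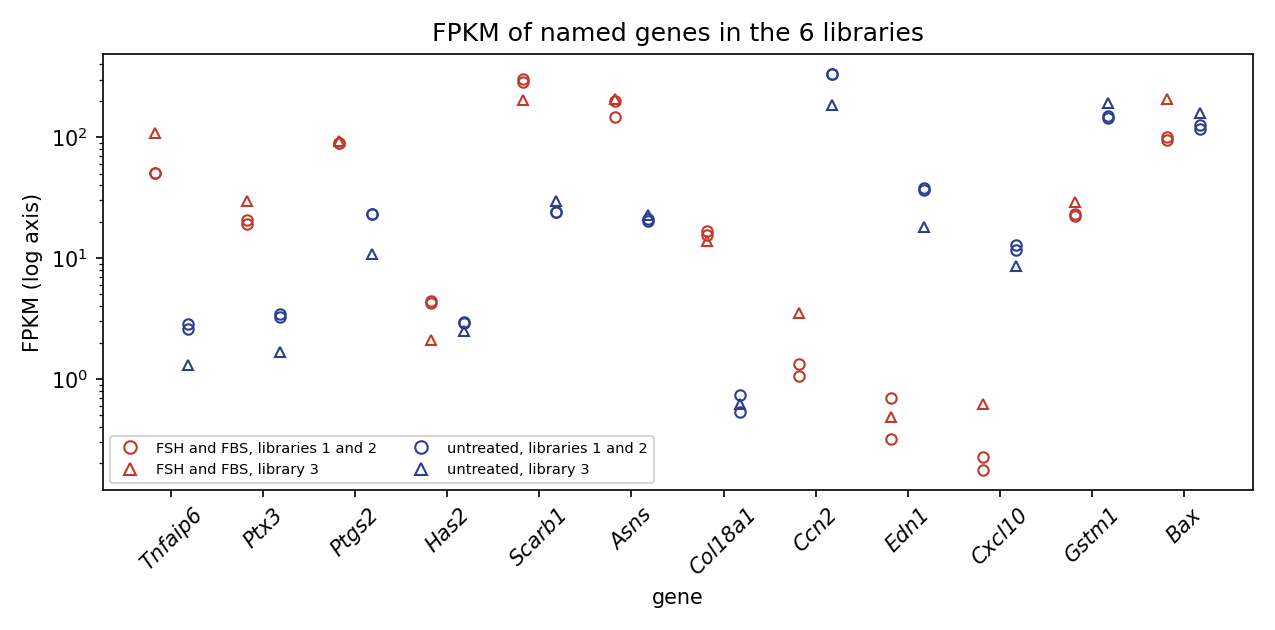
FPKM of 12 named genes (log axis) in each library, with FSH and FBS in red, untreated in blue, circles for libraries 1 and 2 and triangles for library 3. Tnfaip6 lies at a mean of 79.6 FPKM after FSH and FBS and 2.01 in untreated cells, while the groups overlap for Bax.

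The 10 largest rises began with Nts and Cth. Nts, the precursor of neurotensin, had a log2 fold change of 5.63, and Cth, which makes cysteine by transsulfuration, one of 5.21. Spp1, encoding osteopontin, went from 282.7 ± 0.65 to 8442 ± 4441 FPKM (SD, n = 2) and was the gene with the highest FPKM in every FSH and FBS library. Its call was lost under median-of-ratios rescaling. Chac1, which degrades glutathione, and Psat1, a serine synthesis enzyme, rose by 4.22 and 4.07 on the log2 scale. Pla1a, a phospholipase, Ramp1, a receptor partner for calcitonin gene-related peptide, and Lin7b had log2 fold changes of 4.40, 4.36 and 4.10; the Ramp1 call was also lost under that rescaling.

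Among the largest falls after Ccn2 were Fhl1, a LIM-domain protein of muscle, at -5.15, Cnmd, encoding chondromodulin, at -4.86, and Ddit4l at -4.71. Edn1, the precursor of the vasoconstrictor endothelin 1, went from 27.6 ± 13.4 to 0.497 ± 0.018 FPKM (SD, n = 2; log2 fold change -4.17). Pik3ip1, an inhibitor of PI3 kinase, had a log2 fold change of -4.31. Gstt1, a glutathione transferase, Smoc2, a matrix protein, and the imprinted gene Nnat had log2 fold changes of -3.85, -3.60 and -3.55. The Cnmd call was lost when libraries were scaled to equal sums.

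Of 7 tested genes of cumulus expansion, 3 rose and none fell (6 and 0 adjusted over the list alone), and the list moved up (camera adjusted p = 6.15e-05, and adjusted p = 0.50 with an estimated correlation). Besides Tnfaip6, Ptx3, a pentraxin that stabilises the matrix, went from 2.49 ± 1.18 to 24.7 ± 6.77 FPKM (SD, n = 2), and Ptgs2, the inducible prostaglandin synthase, from 17.0 ± 8.77 to 91.4 ± 1.96 FPKM (SD, n = 2), with limma adjusted p of 0.013 and 0.027. The Ptgs2 call was lost under each of the 3 rescalings, and the Ptx3 call when scaled to equal sums. Has2, the hyaluronan synthase of expansion, was at 3.23 ± 1.60 against 2.71 ± 0.32 FPKM (SD, n = 2) and did not pass (limma adjusted p = 0.90). Its direction turned under 2 of the rescalings. Vcan, a matrix proteoglycan, was at 33.9 ± 15.02 against 7.80 ± 3.96 FPKM (SD, n = 2). It did not pass in the lead fit (limma adjusted p = 0.076), though it did with the replicate block.

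Of 11 tested steroid hormone genes, 5 were higher and none lower (8 and 0 adjusted over the list alone; camera adjusted p = 2.89e-07, and adjusted p = 0.41 with an estimated correlation). Scarb1, the receptor that takes up cholesterol from HDL, went from 27.0 ± 4.17 to 248.8 ± 62.6 FPKM (SD, n = 2). Akr1c18, which inactivates progesterone, Fdx1, the electron donor of side-chain cleavage, and Soat1, which esterifies cholesterol, had log2 fold changes of 3.53, 3.09 and 2.33. Named after their values were seen, Cyp11a1, of side-chain cleavage, was the other call, at 200.6 ± 45.2 against 49.4 ± 13.1 FPKM (SD, n = 2, limma adjusted p = 0.046). Hsd3b1 and Hsd17b1 did not pass (limma adjusted p = 0.47 and 0.35). The Cyp11a1 call was not followed under other settings. Of 20 tested cholesterol synthesis and uptake genes, 6 were higher and none lower (18 and 0 adjusted over the list alone; camera adjusted p = 4.15e-12, and adjusted p = 0.47 with an estimated correlation). Msmo1, an enzyme of the late sterol pathway, and Sqle, squalene epoxidase, had log2 fold changes of 2.74 and 1.87. The Soat1 and Sqle calls were lost under all 3 rescalings and the Fdx1 call by median of ratios.

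Genes of ER stress and the integrated stress response moved up, with 3 of 19 higher and none lower (15 and 0 adjusted over the list alone; camera adjusted p = 5.72e-10, and adjusted p = 0.41 with an estimated correlation). Asns, asparagine synthetase, went from 21.6 ± 1.42 to 189.8 ± 22.9 FPKM (SD, n = 2), and Herpud1, of ER-associated degradation, had a log2 fold change of 1.97. In glycolysis 1 gene rose and 1 fell of 17 (4 and 1 adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.50 with an estimated correlation): Hk2, a hexokinase, at 2.81 and Ldhb, a lactate dehydrogenase, at -2.24. The glycolysis list did not pass without FSH and FBS library 3 (adjusted p = 0.10), with last exon sums only (0.30) or with unlisted genes as 0 (0.057). Of 14 hypoxia-response genes 2 rose, Ndrg1 and the ER oxidase gene Ero1l, and none fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.0026, and adjusted p = 0.50 with an estimated correlation). Vegfa, the vascular growth factor, had a log2 fold change of 2.68. It did not pass in the lead fit (limma adjusted p = 0.053), though it did with the replicate block. The Ero1l call was lost under all 3 rescalings, the Herpud1 and Ndrg1 calls under equal sums and median of ratios, the Hk2 call under equal sums and the Ldhb call under median of ratios.

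Of 18 extracellular matrix genes 4 were higher and none lower (8 and 3 adjusted over the list alone; camera adjusted p = 0.014, and adjusted p = 0.62 with an estimated correlation). The list did not pass at a mean FPKM of at least 5 (adjusted p = 0.34), with first exon sums only (0.23) or with last exon sums only (0.080). Col18a1 and Col6a3, collagen genes, had log2 fold changes of 3.30 and 3.14, Timp1, an inhibitor of matrix metalloproteinases, 3.66, and Tnc, tenascin C, 1.94. Inflammatory and NF-kappaB genes moved down, with 2 of 14 lower and 1 higher (6 and 2 adjusted over the list alone; camera adjusted p = 4.28e-06, and adjusted p = 0.62 with an estimated correlation). The chemokine gene Cxcl10 went from 10.4 ± 2.62 to 0.412 ± 0.298 FPKM (SD, n = 2), the cytokine gene Il1a had a log2 fold change of -3.02, and the member that rose was Ptgs2. Leukocyte markers, of which 3 of 15 were tested and none called, summed to 10.8, 9.11 and 12.6 FPKM in the untreated libraries and to 4.18, 3.01 and 8.01 after FSH and FBS. The Il1a and Tnc calls were lost under all 3 rescalings and the Timp1 call under median of ratios.

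Apoptosis genes showed no group shift that passed. Of 22 pro-apoptotic genes none was called (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.69), and of 9 anti-apoptotic genes none was called (0 and 0 adjusted over the list alone; camera adjusted p = 0.69). Bax, an effector of mitochondrial apoptosis, was at 151.2 ± 76.8 FPKM after FSH and FBS and 139.6 ± 25.9 in untreated cells (SD, n = 2). Fas, the death receptor, was at 2.02 ± 1.58 against 5.71 ± 0.51 FPKM (SD, n = 2; limma adjusted p = 0.24). Bcl2 was listed in 1 library, untreated library 3, at 1.92 FPKM. The p53 targets lay lower than other genes as a list (median log2 fold change -0.055) with no called member among 17 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.028, and adjusted p = 0.70 with an estimated correlation). The SMAD list also lay lower (median -0.12), with Ccn2 as its 1 called member of 19 (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.031, and adjusted p = 0.80 with an estimated correlation). By median of ratios neither list passed (adjusted p = 0.056 for each), nor with unlisted genes as 0 (0.070 for p53 and 0.076 for SMAD). The p53 list also did not pass at a mean FPKM of at least 5 (0.12) or with first exon sums only (0.081), and the SMAD list did not when scaled to equal sums (0.053) or without FSH and FBS library 3 (0.15). Leaving out 1 library took the p53 median from -0.055 to between -0.434 (without untreated library 3) and -0.018 (without untreated library 2), with -0.407 without FSH and FBS library 3. The SMAD median went to -0.268 without untreated library 3 and -0.070 without FSH and FBS library 3.

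Among the other lists, Runx1 and Runx2, transcription factor genes of the gonadotropin list, rose, with 2 of 11 members higher and a camera adjusted p of 0.84. In the oxidative stress list Mt2, a metallothionein, and Srxn1, sulfiredoxin, rose and Gstm1, a glutathione transferase, fell, 3 of 17 called (camera adjusted p = 0.33). The Runx1, Mt2 and Srxn1 calls were lost under all 3 rescalings, and the Runx2 call under equal sums. Wt1, a transcription factor of granulosa cells, was lower, the 1 call among 9 identity genes, whose camera direction was down while the median was 0.60 (camera adjusted p = 0.70), and its call was lost under equal sums and median of ratios. None was called of the 10 genes tested from the list of EGF-like factors and ERK targets or of the 18 autophagy, 27 cell cycle, 10 oocyte-dependent, 8 interferon, 8 junction and 12 microRNA biogenesis genes tested, with camera adjusted p of 0.90, 0.69, 0.61, 0.51, 0.19, 0.057 and 0.85. The 4 EGF-like factor genes were not tested, since none was listed in every library; they and Fosl1 are named after their values were seen. Ereg was at 8.89, 9.55 and 16.5 FPKM after FSH and FBS and at 0.67 in 1 untreated library, Areg at 2.46, 3.70 and 13.1 against 0.66 and 0.19 in 2, and Btc at 5.78, 7.24 and 9.30 against 1.819 and 1.501 in 2. Hbegf was at 0.71 and 0.67 FPKM in 2 FSH and FBS libraries against 2.99, 2.73 and 1.24. Fosl1, an ERK target not tested for the same reason, was at 4.33, 3.84 and 9.37 FPKM against 0.87 and 0.66 in 2. Adjusted over the list alone, 4 gonadotropin genes were higher and 3 lower, 3 oxidative stress genes higher and 1 lower, 3 identity genes higher and 1 lower, and 3 oocyte-dependent genes higher.

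Markers of other cells differed between the groups and between libraries. The 25 oocyte markers summed to 34.7, 36.6 and 42.7 FPKM in the untreated libraries and to 32.6 in FSH and FBS library 3, but to 2.53 and 3.15 in FSH and FBS libraries 1 and 2. Acta2, of smooth muscle actin, was the 1 called theca and stroma marker, at 15.8 ± 2.41 against 62.8 ± 6.25 FPKM (SD, n = 2; list camera adjusted p = 0.34). The 3 tested leukocyte markers, Lyz2, Tyrobp and Fcer1g, moved down as a list with no call (0 and 0 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.50 with an estimated correlation), and the list did not pass under quantile normalization (adjusted p = 0.065). Of 15 leukocyte markers, 8, 5 and 6 were listed in the FSH and FBS libraries and 6, 4 and 4 in the untreated ones. Lyz2 alone held 5.98, 5.53 and 7.55 FPKM of the untreated sums and 2.26, 1.84 and 3.76 of the others. Endothelial markers summed to 3.37, 2.81 and 2.70 FPKM in the FSH and FBS libraries and to 0.022, 0.52 and 0.98 in the untreated ones. These endothelial sums rest on 2 of 10 markers in each FSH and FBS library and on 1, 3 and 1 in the untreated ones. Erythroid markers summed to at most 1.92 FPKM in any library. Ribosomal protein genes moved down as a list with none of 26 called (0 and 0 adjusted over the list alone; camera adjusted p = 0.028, and adjusted p = 0.80 with an estimated correlation), and their list did not pass by median of ratios (adjusted p = 0.075), with last exon sums only (adjusted p = 0.072) or without untreated library 3, where the median was 0.089.

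The mean retained share of introns lay lower in both FSH and FBS samples than in both untreated samples. A form that a library did not list counted as 0 in its shares. FSH and FBS library 3 listed the fewest events, 63940 against 68742 to 85853 in the others, and had the lowest mean share. Whether unlisted forms made part of the difference was not tested. Over 1901 matched introns the mean retained share was 9.65% ± 3.48 after FSH and FBS and 16.7% ± 2.83 in untreated cells (SD, n = 2; exact permutation p = 0.333, the smallest that this test can give here, so it decides nothing). The share of 513 introns was lower in both FSH and FBS samples than in both untreated ones, and that of 40 was higher. With no tied shares, 33.3% of introns would separate the groups by chance, and these counts stayed below that. Forms counted as 0 can tie shares, which lowers that rate, and the rate with ties was not computed. The counts therefore cannot decide whether more introns separated than by chance. Most of the introns that separated were lower. Over 3503 cassette exons the mean included share was 56.4% ± 0.51 and 57.7% ± 0.23 (SD, n = 2). The share of 465 was lower and that of 295 higher in both FSH and FBS samples than in both untreated ones. The cassette exon counts also stayed below 33.3% of the exons, and for the same reason they cannot decide this either.

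**Figure D2:**
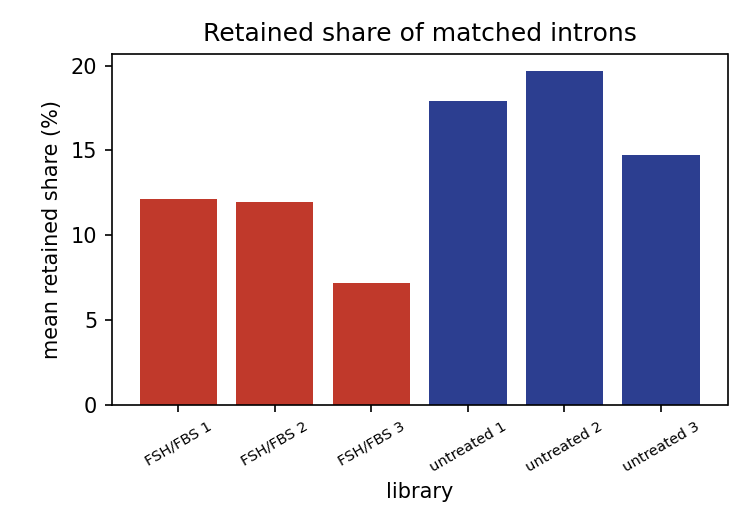
Mean retained share (percent) of 1901 matched introns in each library, FSH and FBS in red and untreated in blue. The bars stand at 12.1%, 11.98% and 7.20% for FSH and FBS libraries 1, 2 and 3 and at 17.9%, 19.7% and 14.7% for the untreated ones.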

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

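All tests in this part were chosen after the result was seen, except the second oocyte gene list. Some genes outside those compared were listed in 1 group only: 140 genes were listed in all 3 FSH and FBS libraries and in no untreated library, and 150 genes the other way round. The other 9 ways to part the 6 libraries into 3 and 3 gave 4 to 55 and 7 to 37 genes. All but 1 of them part libraries 1 and 2 of a group, which leaves few genes to be listed on 1 side only. The 1 that keeps them together, FSH and FBS libraries 1 and 2 with untreated library 3, gave 19 and 21 genes. A single such split cannot decide how far 140 and 150 exceed chance. Chosen after their values were seen, Bmp2, a growth factor gene, had 58.5 ± 21.7 FPKM (SD, n = 2) in untreated samples, and Pkd1l2 had 10.6 ± 2.72 FPKM (SD, n = 2) in FSH and FBS samples.

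Libraries 1 and 2 of each group were closer than other pairs. Over 2045 genes with matching first-exon and last-exon sums the higher residual CV of the 2 pairs was 2.18%, while no other pair within a group fell below 21.6%; over all genes tested the values were 3.76% and 23.5%. Some genes differed widely, with 2.82% and 4.54% beyond 2-fold. Whether 1 sample was measured more than once or cultures were run side by side cannot be told apart, because no counts give the sampling noise.

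Oocyte transcripts were present in the untreated libraries and in FSH and FBS library 3. In a second list of 23 oocyte genes, the fewest listed in these 4 libraries exceeded the most in the other 2 by 8, so RNA from oocytes is a candidate source. A longer gene list in library 3 is argued against, since its count differed by -890 from the lower of libraries 1 and 2. Whether oocytes remained by design in some samples was not tested.

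More genes were higher than lower. The share of higher genes was 71.0% with the deposited FPKM and at most 58.1% under the 3 rescalings. Leaving out untreated library 3, with no rescaling, took the median log2 fold change of all genes from 0.24 to 0.13. Summed gene FPKM was 390966 in FSH and FBS library 3 and 264904 to 274530 in the other libraries. Rescaling that centres the fold changes evens out the calls whether or not a shift is real, so the normalization was not tested as its source. FPKM are relative to the reads of each library, so a rise in total RNA per cell would not show in them. The splits of the 4 samples are 3, too few for a share under 0.05. The real split gave 152 higher and 62 lower genes, and the highest of the other splits gave 0 and 0, with 1 split as large in each case.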

How the results depend on the processing

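The fit of 6 separate libraries, fixed before the data were examined, called 973 higher and 350 lower genes; settings on gene values, unlisted genes, introns and the averaging of libraries were chosen after seeing the data. Estimating the correlation within pairs of libraries gave 162 and 63, against 152 and 62. Same-numbered samples deviated together (r = 0.51 over genes after averaging). The difference between library 3 and libraries 1 and 2 was thus partly shared by both groups, and the lead fit leaves it in its error. No label says that a number marks a shared batch, so the lead fit has no block. With only 2 such pairs left, the block rests on few residual degrees of freedom. The replicate block gave 1040 and 407, and 6 separate libraries with the block 1516 and 584. With the block 40 named genes without a call passed, Vcan, Vegfa and Fas among them, and so did the junction list (adjusted p = 0.049, against 0.80 with an estimated correlation); with 6 libraries and the block the extracellular matrix (0.076) and SMAD lists (0.061) did not. Of the named genes without a call, 37 passed with 6 separate libraries and 44 with 6 separate libraries and the block. Scaling to equal sums gave 54 and 39, median of ratios 49 and 41, and quantile normalization 93 and 72. First-exon sums alone gave 42 and 21 (7942 genes tested), the largest of any event 221 and 97, and events tested one by one 78 and 40. Leaving out 1 library gave 42 to 253 higher and 33 to 131 lower, the extremes without untreated library 3 and FSH and FBS library 3, where the lone sample is assumed to vary like the other group. The 12 lists past the threshold became 0 with an estimated correlation. With fry, which tests a list against no change and not against other genes, 1 of them passed. First-exon sums alone ended 17 of the 45 calls of named genes, unlisted genes as 0 ended 8, and an estimated correlation within pairs ended 6. No called named gene changed direction under a setting that tested it (37 to 45 of the 45 genes). Some genes without a call and 2 lists did. Under scaling to equal sums, median of ratios and quantile normalization, log2 fold changes were -0.28, -0.24 and -0.48 for Bax, -0.23, -0.17 and -0.15 for Tagln, and -0.21, -0.17 and -0.20 for the median of pro-apoptotic genes; Has2 was at -0.11 and -0.060 under the first 2. With 6 separate libraries, blocked or not, Bax was at -0.089 and Tagln at -0.11, and with first-exon sums Tagln was at -0.020. Leaving out 1 library, Bax ranged from -0.51 to 0.22, Rpl18 from -0.41 to 1.12, Tagln from -0.22 to 0.14, and the ribosomal protein median from -0.71 to 0.089. The cause was not tested. The difference in retained introns stayed at -5.96 points from 5 FPKM and -7.05 points without called genes, against -7.07. Count-based tools were not run, since the files hold no counts. Depth is unknown, and what it limits was not tested; only genes listed in every library were tested.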

Other observations

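All tests in this part were chosen after the result was seen, and each group is a hypothesis. Serine and one-carbon enzymes may have risen as a group after FSH and FBS: without Psat1 and Cth, which prompted the list, 6 of 11 tested genes were higher and none lower (camera p adjusted over 4 lists 9.83e-06; adjusted p = 0.10 with an estimated correlation). Phgdh, the first enzyme of serine synthesis, went from 22.6 ± 0.86 to 195.6 ± 66.8 FPKM (SD, n = 2), and Mthfd2, of mitochondrial folate metabolism, from 7.19 ± 0.57 to 96.4 ± 7.32 FPKM (SD, n = 2). Aminoacyl-tRNA synthetase genes, which charge tRNAs, lay higher in both samples in 11 of 11 cases, with Lars the 1 called (camera p adjusted over 4 lists 1.73e-07; adjusted p = 0.10 with an estimated correlation). Both results stay open. They did not pass with an estimated correlation, and that form of the test has too few residual degrees of freedom to decide.

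Although Ccn2, a target of YAP and TEAD, had the largest fall, 7 other tested YAP and TEAD targets did not pass as a group (camera p adjusted over 4 lists 0.72), and none was called. Although Acta2 fell, 10 other tested SRF and actin cytoskeleton targets did not pass either (camera p adjusted over 4 lists 0.11), and their median log2 fold change was 0.48.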
